A study of Arabidopsis thaliana with 15 samples.

How the data were processed

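RNA from roots of 5 genotypes, 3 samples each, was hybridised to 15 Affymetrix-type arrays of 22810 probe sets. The deposited values are intensity on a linear scale, computed by the authors with MAS5 per the submitters' processing notes, with no version given in the sources used here. The 2% trimmed mean was near-equal on all arrays, signals ran from 0.00117 to 32792, and no detection calls were used here. Samples were grouped by the labels. No 2 arrays held identical values, and the highest correlation between a pair was 0.9621.

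Values were taken to log2 with no offset and no further normalization, since array medians differed by 0.149, under the limit set for centring. The 64 control probe sets were left out of the tests. A probe set was tested if its mean log2 signal reached the 40th percentile of the 22746 others (6.845, a signal of 115), which left 13648. Of the 22746, 13513 have 1 gene in the annotation table, 503 several and 8730 none. Of those tested the numbers are 7346, 287 and 6015, and probe sets with several genes or none were tested but not named. The names of 13436 matched a reference gene table of assembly TAIR10.1, which was used for names and gene order only. A gene with several probe sets is given by the brightest. Of 42 such genes 3 had calls in opposite directions.

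Group means were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, tables read by data.table, version 1.17.8). All tests are two-sided, and a probe set was called at an adjusted p under 0.05 (Benjamini-Hochberg). Every adjusted p of a gene is from limma. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation. No list passed 0.05 after adjustment with the estimated correlation. Overlaps of calls were set against the product of the list sizes over the probe sets tested, and covariances against 20 simulations of unchanged groups on the same arrays. Each simulation gave a probe set the same spread in all groups.

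Of 24 lists fixed before the data were examined, with 362 entries, 45 entries were named on the array, and 2 lists, the expansins and the photosynthesis genes, had the 3 members that a test needed. Members whose symbol in the reference contradicted the list (5) were left out. A further 20 lists were added after the annotation was seen and before any comparison was computed. They are cytosolic ribosomal proteins, core histones, class III peroxidases, extensins, TIR-domain genes, ER bodies and jacalins, glutathione transferases, UDP-glycosyltransferases, CYP71B, SWEET, beta-glucosidases, xyloglucan endotransglucosylases, TBL, tetraspanins, serine carboxypeptidase-like, U-box ligases, ATG8, GH9 cellulases, plastid-encoded and mitochondria-encoded genes.

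Genes were named by a rule fixed before the data were examined: the 8 higher and 8 lower with the largest changes in each main comparison (called, with no overlap between the arrays of the groups), the 4 per direction for differences and overlaps, and up to 4 called members per list. For the comparisons of P35S:rGRF3 with Col-0, the within-set overlap of the mutant and P35S:rGRF1, and genes changed alike in both lines, like rules were written after the data were seen. Values of such genes in further comparisons, and genes named for what they encode, were also chosen then.

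The calls were tested on simulated data for P35S:rGRF1 against Col-0 over 13648 probe sets. Of probe sets changed 1.5-fold 49.25% were called, of those changed 2-fold 95.52%, of those changed 4-fold 100%, and 5.202% of the calls were false. Noise was drawn independently for each probe set, with the same spread in all groups. The real Col-0 arrays varied more than those of P35S:rGRF1, so these rates need not hold for the real calls.

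Alternatives fixed in advance were no filter or the 60th percentile, an offset of 16, quantile normalization, no trend, robust fitting, array weights, a replicate block, only the groups compared, a minimum change of 1.5-fold, and leaving out each array in turn. Added after the data were seen were Col-0 as the control for P35S:rGRF3, comparisons within array sets, and the poly-A control signal as a covariate.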

Results

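Transcript levels in roots of 2-week-old Arabidopsis thaliana plants were measured on 15 oligonucleotide arrays of 22810 probe sets, 3 arrays for each of 5 genotypes. The wild types were the ecotypes Col-0 and WS. A triple mutant carried mutations in the growth-regulating factor genes GRF1, GRF2 and GRF3, which encode transcription factors, and its labels give both ecotypes. The lines P35S:rGRF1 (labelled Col-0) and P35S:rGRF3 (labelled WS) expressed a form of GRF1 or GRF3 resistant to the microRNA miR396 from the strong 35S promoter. The question, from the title of the series, was which genes GRF1 and GRF3 regulate in roots. The 3 factors themselves were not analysed here, so the labels could not be checked against them. Every array had been scaled to a common mean signal, and the medians of log2 signal spanned 0.149 over the 15 arrays. The number of arrays limits the precision of every value. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples only.

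Control probe sets divided the arrays into 2 sets. The 18 probe sets for RNA added at hybridization averaged 10.89 ± 0.181 (SD, n = 6) on the log2 scale on the WS and mutant arrays and 10.01 ± 0.226 (SD, n = 9) on the Col-0, P35S:rGRF1 and P35S:rGRF3 arrays. The lowest value of the first set, 10.72, lay above the highest of the second, 10.33. The poly-A controls, for RNA added to the sample before labelling, divided the arrays in the same way: the log2 signal of their 3' minus that of their 5' probe sets was 2.22 ± 0.27 (SD, n = 3) in WS and 2.04 ± 0.21 in the mutant. It was 1.55 ± 0.12 in Col-0, 1.66 ± 0.15 in P35S:rGRF1 and 1.62 ± 0.11 in P35S:rGRF3. WS against Col-0, the mutant against Col-0 and P35S:rGRF3 against WS therefore compare arrays of different sets, and in these comparisons array set and genotype cannot be told apart. The mutant against WS, P35S:rGRF1 against Col-0, and P35S:rGRF3 against Col-0 each lie within 1 set and are given first where both exist. Within the sets, too, the hybridization controls separated some genotypes without overlap. They read 10.85 to 11.2 in WS and 10.72 to 10.81 in the mutant, and 9.679 to 10 in Col-0 and 10.07 to 10.18 in P35S:rGRF1. Comparisons within 1 set are therefore not free of technical differences that go with genotype. Use of Col-0 as a control for P35S:rGRF3 was added after the data were seen. The probe set for 25S ribosomal RNA read 12.21 ± 0.35 (SD, n = 3) in Col-0, 11.56 ± 0.14 in WS, 10.27 ± 0.52 in the mutant, 12.88 ± 0.04 in P35S:rGRF1 and 11.68 ± 0.63 in P35S:rGRF3.

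**Figure D1:**
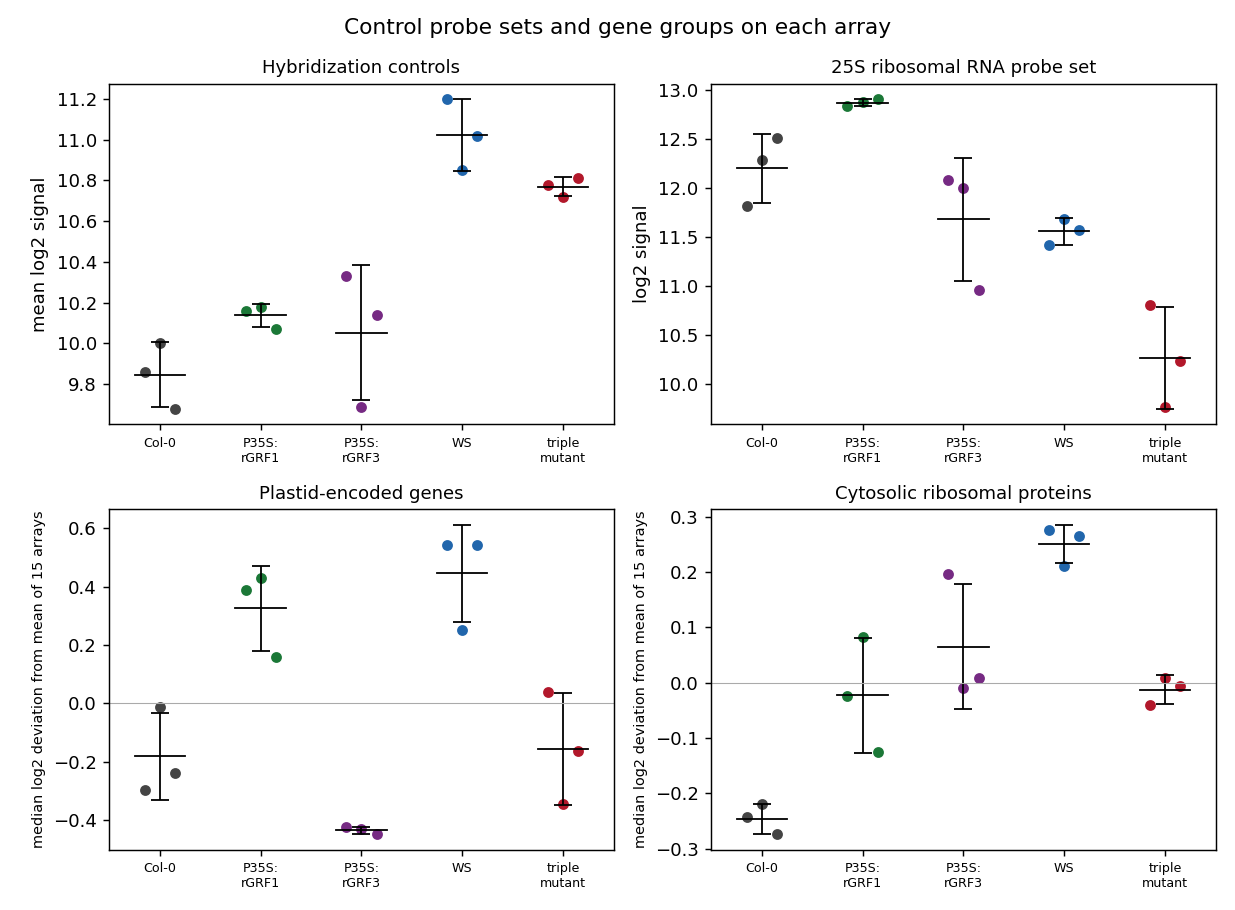
Log2 signal of the hybridization controls and of the 25S ribosomal RNA probe set, and scores of the plastid-encoded and ribosomal protein genes (median log2 deviation from the mean of the 15 arrays), for each array (points) by genotype, with the mean (line) and SD (bar) of 3 arrays. The hybridization controls of the WS and mutant arrays all lie at or above 10.72, and those of the other arrays at or below 10.33.

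Among the largest differences between the wild types were those of 2 oxidase genes. AT1G26390 and AT1G26380, which encode berberine bridge enzyme-like oxidases, read 12.64 ± 0.50 and 12.48 ± 0.31 (log2 signal, SD, n = 3) in Col-0 and 1.59 ± 1.1 and 4.72 ± 0.40 in WS. Their log2 differences of WS from Col-0 were -11.06 (SE 0.44, adjusted p = 1.84e-11) and -7.76 (SE 0.18, adjusted p = 4.45e-14). The germin-like gene AT5G38910 (-7.32), the class III peroxidase gene AT5G64120 (-5.62), the histone H2B gene HTB11 (-4.52), the lectin gene JAL33 (-4.01) and the TIR-domain gene AT5G45220 (-4.02) were also lower in WS. AT2G15560 (5.41, SE 0.27) and AT1G50290 (4.42, SE 0.17) were higher. GI, a component of the circadian clock, was higher in WS by 0.94 (adjusted p = 8.08e-06).

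Among gene groups, 83 of 101 genes for cytosolic ribosomal proteins were higher in WS than in Col-0 and 4 lower, with a median of 0.51 (adjusted p = 4.76e-08 for the list, and adjusted p = 0.497 with an estimated correlation). Of 42 plastid-encoded genes 25 were higher and 5 lower (adjusted p = 0.038, and 0.610 with an estimated correlation). Of 7 CYP71B cytochrome P450 genes 6 were lower, led by CYP71B26 at -3.17 (adjusted p = 6.15e-04, and 0.0881 with an estimated correlation). Of 39 class III peroxidase genes 16 were lower and 6 higher (adjusted p = 0.00396, and 0.288 with an estimated correlation). TIR-domain genes were lower at 7 and higher at 3 of 14 (adjusted p = 0.105), and the list passed with no filter on dim probe sets (adjusted p = 0.0167). UDP-glycosyltransferase genes were lower at 9 and higher at 4 of 25, UGT72E1 by -1.81 (adjusted p = 0.0251, and 0.193 with an estimated correlation). In all, 7058 of 13648 probe sets differed, 4292 higher and 2766 lower in WS, and 321 by at least 4-fold. The comparison crosses the array sets, with a 3' minus 5' difference of the poly-A controls of 2.22 in WS and 1.55 in Col-0 beside all these gene groups. The probes were designed from Col-0 sequence, so a WS allele can also read low through mismatch, and folds against dim signals such as 1.59 depend on noise.

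MTPA1 (AT3G61940), a metal transporter gene, was among those that fell in the triple mutant against both wild types. It read 2.96 ± 1.5 (log2 signal, SD, n = 3) in the mutant, 6.56 ± 0.68 in WS and 6.75 ± 0.38 in Col-0, a fall of -3.60 against WS (SE 0.53, adjusted p = 4.13e-04) and of -3.78 against Col-0. These means lie below the filter value of 6.845. MTPA1 passed the filter through the overexpression lines, whose arrays read 8.411 to 10.01, so the size of its fall depends on noise. BCAT4, an aminotransferase of the synthesis of methionine-derived glucosinolates, fell, at -3.49 against WS (SE 0.54, adjusted p = 5.68e-04) and -3.175 against Col-0. AT2G31790, a glucosyltransferase gene of the same pathway, fell (-1.71 and -1.63), as did the zinc transporter gene ZIP9 (-1.43 and -1.21) and the subtilase gene SBT4.12 (-2.07 and -1.28). AT1G36640, AT1G56680 and AT5G48430 fell against WS (-2.64, -2.83 and -2.20) and against Col-0 (-5.46, -3.83 and -2.90).

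Genes that rose in the mutant against both wild types included the nitrate transporter family gene AT3G21670 (3.16 against WS, SE 0.34, and 1.31 against Col-0) and the proline dehydrogenase gene AT5G38710 (2.34, SE 0.20, and 1.43). The signalling peptide gene CLE26 rose by 1.65 (SE 0.26) and 1.37, and the phosphoglycerate mutase-like gene AT5G04120 by 1.53 (SE 0.37) and 1.22. The calls of AT5G04120 were lost against WS without WS replicate 1 (1.38, adjusted p = 0.0536) and against Col-0 without Col-0 replicate 3 (0.86, adjusted p = 0.0762). NRT2.5, a high-affinity nitrate transporter gene, rose by 3.57 against WS (SE 0.43, adjusted p = 7.95e-05), and its difference from Col-0 was 0.23 (adjusted p = 0.692). AT3G25790, for a Myb-family transcription factor, fell by 3.54 against WS (adjusted p = 2.40e-05), with a difference of -0.81 from Col-0 (adjusted p = 0.0766). Against both wild types in 1 direction, 675 probe sets changed, 341 higher and 334 lower, and 1179 with weights for the arrays. Against WS, within 1 array set, 1900 changed, 1007 higher and 893 lower. That count was 1259 without WS replicate 1, 1158 without WS replicate 3 and 1197 without mutant replicate 2. Against Col-0, across the sets, it was 6161, 3838 higher and 2323 lower.

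Plastid-encoded genes and genes for ribosomal proteins fell together in the mutant against WS. Of the 42 plastid-encoded genes 22 fell and none (0) rose, with a median of -0.69 and psbA at -1.28 (SE 0.26), psaB at -1.13 and atpA at -1.04. The list passed the test (adjusted p = 1.13e-14), with adjusted p = 0.156 with an estimated correlation. Of the nuclear genes of photosynthesis 3 of 5 fell, PSBW (-1.1), LHCB4.1 (-0.88) and PSBY (-0.67), and 4 when adjusted over the list alone (adjusted p = 0.00668 for the list, and 0.275 with an estimated correlation). Of 101 ribosomal protein genes 35 fell and 1 rose, with a median of -0.29 (adjusted p = 1.75e-13, and 0.234 with an estimated correlation). The 25S ribosomal RNA probe set moved the same way, at -1.29. Against Col-0 the plastid-encoded genes went both ways, 11 higher and 13 lower (adjusted p = 0.314), and 46 ribosomal protein genes were higher and 6 lower (adjusted p = 0.0849). The ribosomal list passed there with no filter on dim probe sets (adjusted p = 0.00453) and after quantile normalization (adjusted p = 0.0393).

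Expansins, which loosen the cell wall, rose in the mutant against WS at 4 of 7 genes, and at 5 when adjusted over the list alone: EXPA8 by 1.24 (SE 0.21), EXPA15 by 1.08, EXPB3 by 0.63 and EXPA4 by 0.55. The list passed the test (adjusted p = 1.1e-04, and 0.201 with an estimated correlation). Against Col-0, 4 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.641). UDP-glycosyltransferase genes rose at 8 of 25 and none (0) fell, with UGT72E2 at 1.30, UGT72E3 at 0.98 and UGT71C1 at 0.75 (adjusted p = 0.0011, and 0.0871 with an estimated correlation). Genes of ER bodies and jacalin-related lectins rose at 3 of 6, NAI1 by 0.78, JAL22 by 0.59 and NAI2 by 0.52 (adjusted p = 0.00142, and 0.201 with an estimated correlation). Of 7 extensin genes 1 fell, and the list median was -0.56 (adjusted p = 0.0102, and 0.244 with an estimated correlation). These lists did not pass against Col-0. There UDP-glycosyltransferase genes were higher at 6 and lower at 8 (adjusted p = 0.635 for the list). ER body and jacalin genes were higher at 2 and lower at 2 (0.866), as were extensins (0.641). Lower than Col-0 were 5 of 7 CYP71B genes (adjusted p = 0.00147, and 0.119 with an estimated correlation), 18 of 39 peroxidase genes, with 5 higher (adjusted p = 8.95e-04, and 0.135), and 8 of 14 TIR-domain genes, with 2 higher (adjusted p = 0.0242, and 0.119). These values cross the array sets, where the 3' minus 5' difference was 2.04 in the mutant and 1.55 in Col-0. In WS against Col-0, too, most called members of these lists were lower. Against WS, within 1 set, the mutant had 0 of 7 CYP71B genes past the threshold (adjusted p = 0.510 for the list). Peroxidase genes were higher at 3 and lower at 6 there (0.787), and TIR-domain genes at 0 and 2 (0.167).

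The largest fall in P35S:rGRF1 against Col-0 among the named genes was that of NRT2.5. It read 10.48 ± 1.1 (log2 signal, SD, n = 3) in Col-0 and 4.91 ± 0.39 in the line, a change of -5.56 (SE 0.43, adjusted p = 3.46e-06). AT5G04120 fell by 4.34 (SE 0.37, adjusted p = 8.38e-06), from 11.41 ± 0.79 to 7.08 ± 0.84. The sugar transporter genes SWEET14 (-3.31, SE 0.43) and SWEET13 (-1.78, SE 0.30) fell, as did OCT1 (-2.44, SE 0.35), AT4G33040 (-2.45, SE 0.26), AT3G21670 (-1.85) and UGT76D1 (-1.36). On the P35S:rGRF1 arrays NRT2.5 read 4.479 to 5.24 and SWEET14 read 5.742 to 6.442, below the filter value of 6.845. The sizes of the falls of NRT2.5 and SWEET14 therefore depend on noise. The defensin gene PDF2.1 rose by 2.48 (SE 0.30, adjusted p = 2.42e-04), AT2G01610 by 2.08 and AT3G25790 by 2.07 (SE 0.36). MTPA1 rose by 2.36 (SE 0.53, adjusted p = 0.0115), BCAT4 by 2.20 (SE 0.54, adjusted p = 0.0182), SBT4.12 by 1.26, AT2G31790 by 1.2, GSTU20 by 1.17 and ZIP9 by 1.15.

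Without Col-0 replicate 1, BCAT4 was at 1.69 (adjusted p = 0.0809) and SBT4.12 at 0.78 (adjusted p = 0.0514). With any P35S:rGRF1 array left out the fold of BCAT4 stayed near its value while the call was lost, at 2.21 (adjusted p = 0.0578), 2.24 (0.0501) and 2.17 (0.0576) without replicates 1, 2 and 3. MTPA1 lost its call without P35S:rGRF1 replicate 1 (2.24, adjusted p = 0.0502) or 2 (2.13, adjusted p = 0.0506), and ZIP9 without replicate 2 (0.96, adjusted p = 0.0726). SBT4.12 lost its call at 1.27 without P35S:rGRF1 replicate 1 (adjusted p = 0.0574) and at 1.16 without replicate 3 (adjusted p = 0.0682). It also lost it with the poly-A covariate (1.31, adjusted p = 0.0519) and with only the arrays of the 2 groups compared (1.26, adjusted p = 0.0671). With robust fitting BCAT4 lost its call (2.20, adjusted p = 0.0566). In all, 1429 probe sets changed, 724 higher and 705 lower. The count was 658 without Col-0 replicate 1, and 586, 756 and 704 without P35S:rGRF1 replicates 1, 2 and 3. It was 3017 with weights for the arrays, 757 with the poly-A control signal as a covariate and 919 with only the arrays of the 2 groups compared.

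Plastid-encoded genes rose in P35S:rGRF1 at 16 of 42 and none (0) fell, with a median of 0.53. matK rose by 1.35, atpA by 1.33 (SE 0.26), petA by 1.21 and psbK by 1.06 (adjusted p = 2.70e-10 for the list, and 0.240 with an estimated correlation). Ribosomal protein genes rose at 11 of 101 and none (0) fell, with a median of 0.21 and AT5G58420 at 0.57 (adjusted p = 1.07e-08, and 0.520 with an estimated correlation). On the same arrays the 25S ribosomal RNA probe set was higher by 0.67, and the 24 poly-A control probe sets by 0.86. UDP-glycosyltransferase genes fell at 5 of 25 and 1 rose, with UGT78D2 at -0.66, UGT71C1 at -0.60 and UGT88A1 at 0.71 (adjusted p = 0.00540, and 0.0854 with an estimated correlation). SWEET genes had a median of -0.37, with 2 of 7 lower (adjusted p = 0.00540, and 0.0854 with an estimated correlation), a call that was lost with no filter on dim probe sets. ATG8 genes of autophagy had a median of -0.23 with no single member past the threshold (adjusted p = 0.0423, and 0.520 with an estimated correlation), a call that was lost after quantile normalization (adjusted p = 0.0727). EXPA8 (-1.33, SE 0.21) and EXPA18 (-0.54) fell, and when adjusted over the list alone 3 of 7 expansins were higher and 3 lower (adjusted p = 0.392 for the list). No photosynthesis gene (0 of 5) passed in either direction, also when adjusted over the list alone (adjusted p = 0.220 for the list).

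The largest rise in P35S:rGRF3 over both wild types among the named genes was that of AT4G33720, of the pathogenesis-related protein 1 family. It read 12.43 ± 0.28 (log2 signal, SD, n = 3) against 7.26 ± 1.2 in Col-0 and 6.25 ± 0.10 in WS, a rise of 5.17 over Col-0 (SE 0.50, adjusted p = 5.43e-06) and 6.18 over WS. The dirigent family gene AT3G13650 rose by 3.04 (SE 0.17, adjusted p = 1.71e-08) and 3.39, AT1G11540 by 2.30 (SE 0.20) and 2.61, and the peroxidase gene AT3G03670 by 2.80 (SE 0.58) and 3.70. MTPA1 rose by 3.19 over Col-0 (SE 0.53) and 3.38 over WS, ZIP9 by 2.42 and 2.21, NRT2.5 by 2.25 and 5.59, and XTH18, of the xyloglucan endotransglucosylases, by 1.03 and 1.13. AT3G56080 fell against Col-0 (-2.42, SE 0.43) and WS (-4.30), as did AT5G38710 (-2.05 and -1.14), OCT1 (-1.82 and -2.96) and UGT76D1 (-1.36 and -1.57). BCAT4 was at -0.06 (adjusted p = 0.963) and AT5G04120 at -0.24 (adjusted p = 0.741) against Col-0. The arrays of P35S:rGRF3 read 9.711, 8.356 and 11.24 at BCAT4, on both sides of the Col-0 range of 8.807 to 10.39. Its mean difference therefore does not show that BCAT4 was unchanged.

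Ribosomal protein genes rose in P35S:rGRF3 against Col-0 at 42 of 101 and none (0) fell, with a median of 0.32 and AT2G21580 at 0.60 (adjusted p = 1.87e-19, and 0.168 with an estimated correlation). Their scores on replicates 1 to 3 were 0.196, -0.00921 and 0.00875, and -0.243, -0.220 and -0.274 in Col-0. Replicate 3 of P35S:rGRF3 read 6.96 at the poly-A controls and 10.96 at 25S ribosomal RNA, where replicates 1 and 2 read 9.02 and 8.78, and 12.09 and 12. Of UDP-glycosyltransferase genes 6 of 25 fell and 2 rose, UGT72E1 by -2.09 and UGT72E2 by -1.31 (adjusted p = 0.00735, and 0.148 with an estimated correlation). CYP71B genes fell at 3 of 7 and 1 rose, CYP71B6 by -1.79 (adjusted p = 0.0247, and 0.168 with an estimated correlation). Plastid-encoded genes had a median of -0.22 with 1 of 42 lower (adjusted p = 0.0187, and 0.724 with an estimated correlation). With no filter on dim probe sets these 2 calls were lost (adjusted p = 0.441 and 0.0606). No expansin (0 of 7) and no photosynthesis gene (0 of 5) passed, also when adjusted over the list alone. In all 1626 probe sets differed from Col-0, 724 higher and 902 lower, and the count was 973 without Col-0 replicate 2 and 1069 without P35S:rGRF3 replicate 1. With only the arrays of the 2 groups compared it was 621.

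Against WS, the labelled background, 7147 probe sets differed in P35S:rGRF3, 2643 higher and 4504 lower. There 30 of 42 plastid-encoded genes were lower and 4 higher (adjusted p = 0.00235, and 0.622 with an estimated correlation), and all 5 mitochondria-encoded genes were lower (adjusted p = 0.0479, and 0.609 with an estimated correlation). The mitochondrial call was lost after quantile normalization (adjusted p = 0.208), with no filter (0.411) and with 16 added to each value before logs (0.211). Ribosomal protein genes, which rose against Col-0, were lower here at 36 of 101 and higher at 6, with a median of -0.19. Over all probe sets 4504 of 13648 were lower. The ribosomal list did not pass (adjusted p = 0.3, and 0.861 with an estimated correlation), but did after quantile normalization (adjusted p = 0.0306). CYP71B genes were higher at 4 of 7 and lower at 1, with a median of 0.54, and the list did not pass (adjusted p = 0.0547, and 0.427 with an estimated correlation). Peroxidase genes were higher at 17 of 39 and lower at 6 (adjusted p = 0.00235, and 0.427 with an estimated correlation). Expansins were higher at 4 of 7, and photosynthesis genes lower at 3 of 5, the same counts when adjusted over the list alone, and neither list passed (adjusted p = 0.208 and 0.265). These values cross the array sets, where the 3' minus 5' difference was 1.62 in P35S:rGRF3 and 2.22 in WS. At 310 probe sets that separated the wild types by at least 2 on the log2 scale, P35S:rGRF3 lay nearer Col-0 at 91.0%, as did P35S:rGRF1, and the mutant lay nearer WS at 85.2%. AT1G26390 read 11.93 ± 0.10 in P35S:rGRF3 and AT2G15560 read 5.81 ± 0.28, near their Col-0 levels. Against both wild types in 1 direction, 811 probe sets differed, 350 higher and 461 lower.

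The 2 overexpression lines differed from each other, on arrays of 1 set, at NRT2.5 by -7.81 (P35S:rGRF1 minus P35S:rGRF3, SE 0.43, adjusted p = 1.32e-08), AT4G33720 by -6.92, AT5G04120 by -4.09 (SE 0.37), AT3G13650 by -2.96 and SWEET14 by -2.47. NRT2.5 and SWEET14 read below the filter value of 6.845 on the P35S:rGRF1 arrays, so the sizes of their differences depend on noise. AT3G25790 was higher in P35S:rGRF1 by 2.31, BCAT4 by 2.26 (SE 0.54, adjusted p = 0.00799) and AT3G56080 by 2.29. Of the 42 plastid-encoded genes 32 were higher in P35S:rGRF1 and none (0) lower, with a median of 0.81 (adjusted p = 4.69e-13, and 0.314 with an estimated correlation). The photosynthesis genes were higher at 2 of 5, and at 5 when adjusted over the list alone (adjusted p = 0.0403, and 0.485 with an estimated correlation). SWEET genes were lower at 4 of 7 and higher at 1 (adjusted p = 0.0403, and 0.314 with an estimated correlation). Ribosomal protein genes were lower at 7 of 101 (adjusted p = 0.00869, and 0.604 with an estimated correlation). CYP71B genes (3 of 7 higher), mitochondria-encoded genes (3 of 5 higher), ATG8 genes (3 of 9 lower) and wall acetylation genes of the TBL family (3 of 16 lower) each had adjusted p = 0.0403, and 0.320, 0.414, 0.457 and 0.414 with an estimated correlation. In all 2891 probe sets differed, 1713 higher and 1178 lower in P35S:rGRF1, and 1672 without P35S:rGRF1 replicate 1 and 1330 with the poly-A control signal as a covariate. The excess of higher calls was not kept after quantile normalization, with 1272 higher and 1265 lower. With each line set against its labelled background, across the array sets, the effects differed at 6657, 4108 and 2549 of them higher and lower. This contrast also holds the difference between WS and Col-0, called at 7058.

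Both lines changed some genes in 1 direction against Col-0: AT1G20380 rose by 1.36 and 1.90 and MTPA1 by 2.36 and 3.19, while OCT1 (-2.44 and -1.82) and UGT76D1 (-1.36 in each) fell. The calls shared direction at 301 probe sets and opposed at 49, where independent lists would give 85.0 and 85.2. Both comparisons use the same 3 Col-0 arrays. The covariance of the fold changes was 0.0408, and 0.015 in simulated unchanged groups against the same arrays. Their r was 0.266, and 0.5 in those simulations. All groups were simulated with the same spread, though Col-0 arrays varied more than those of P35S:rGRF1, so 0.015 may be too low. Part of the sharing may come from the shared controls. With P35S:rGRF3 against WS instead, 174 shared direction, where 373 would be given by independent lists, and 779 opposed. The 174 became 106 without Col-0 replicate 1, and 96, 98 and 82 without P35S:rGRF1 replicates 1, 2 and 3, and it was 336 with array weights and 108 with the poly-A covariate.

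With WS as the control of the mutant, most genes called in both the mutant and P35S:rGRF1 went opposite ways, which was not so with Col-0 as its control. MTPA1, BCAT4, AT2G31790, ZIP9, SBT4.12, GSTU20, BGLU44 and AT3G25790 were lower in the mutant than in WS and higher in P35S:rGRF1 than in Col-0. NRT2.5, SWEET14, SWEET13, AT3G21670, AT5G04120, AT4G33040, EXLB1 and EXPA8 were higher in the mutant and lower in P35S:rGRF1. EXLB1, an expansin-like gene, stood at 2.31 (SE 0.34) and -1.81 (SE 0.34), and BGLU44, a beta-glucosidase gene, at -1.40 and 1.38. The plastid-encoded genes had medians of -0.69 and 0.53, and the 25S ribosomal RNA probe set stood at -1.29 and 0.67.

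**Figure D2:**
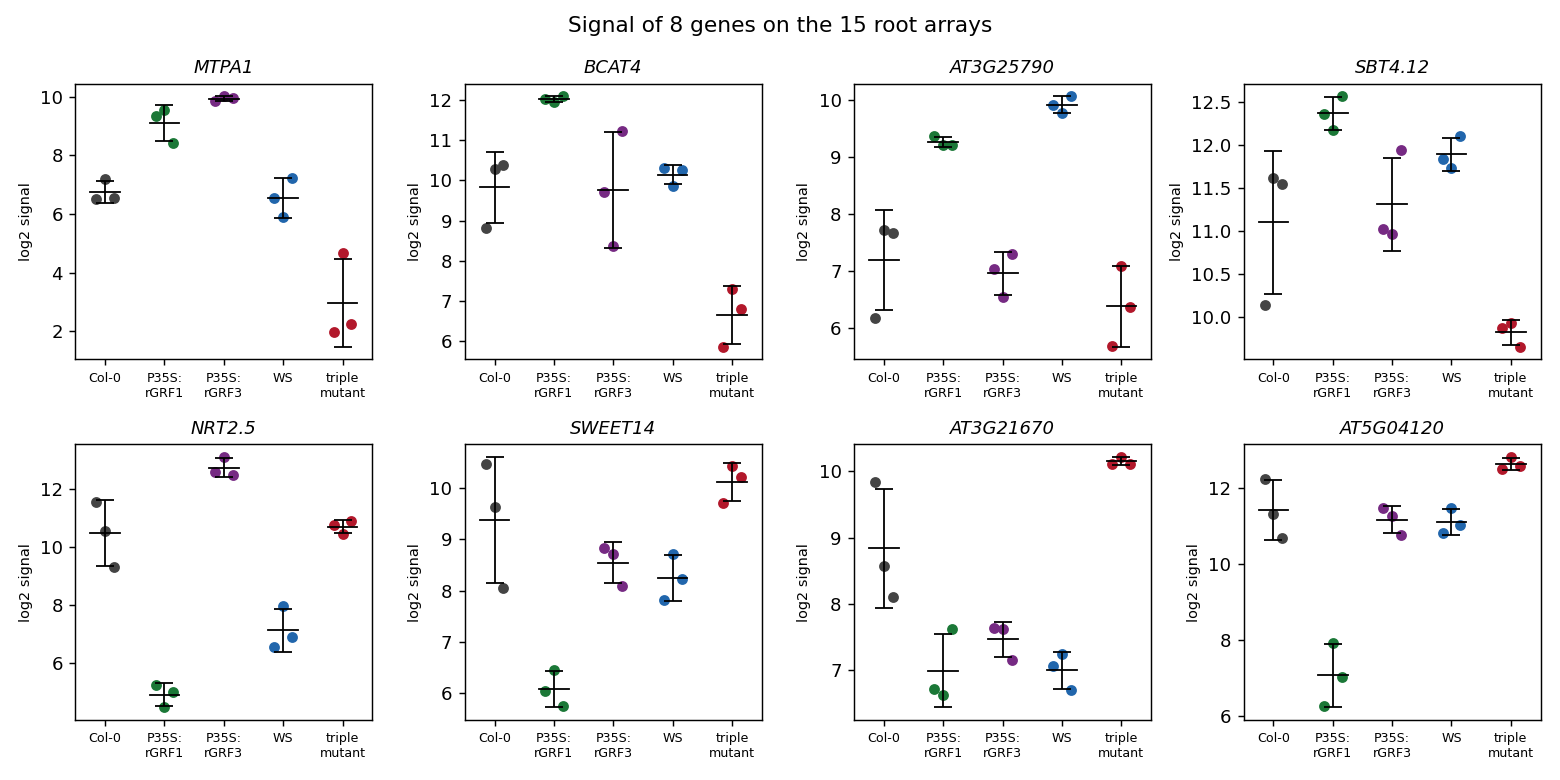
Log2 signal of 8 named genes on each array (points) in the 5 genotypes, with the mean (line) and SD (bar) of 3 arrays. NRT2.5 averaged 4.91 in P35S:rGRF1 and 12.72 in P35S:rGRF3, and MTPA1 averaged 2.96 in the mutant and 9.94 in P35S:rGRF3.

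With the mutant against WS and P35S:rGRF1 against Col-0, which share no arrays and each lie within 1 set, 605 probe sets changed in opposite directions and 13 in the same, where independent lists would give 99.4 and 99.5. Of the 605, 349 were higher in the mutant and 256 lower. Across all 13648 probe sets, which are not independent replicates, the fold changes had Pearson's r of -0.649 and Spearman's rho of -0.559, and r was -0.277 with no filter on dim probe sets. The count was 336 without Col-0 replicate 1, 384 without WS replicate 3, and 322, 337 and 335 without P35S:rGRF1 replicates 1, 2 and 3. It was 1131 with array weights and 369 with the poly-A covariate. With the mutant called against both wild types, 179 opposed and 4 agreed in direction, where independent lists would give 35.3 each, and the Col-0 arrays are shared. With the mutant against Col-0 alone, 551 shared direction and 251 opposed, where independent lists would give 324 and 321. This pair crosses the array sets and shares the Col-0 arrays. The shared arrays alone gave r of 0.5 and a covariance of 0.015 in simulated unchanged groups, and the real values were 0.0728 and 0.0216. Col-0 was simulated with the same spread as the other groups, so 0.015 may be too low for it. WS against Col-0 also crosses the sets and shares the Col-0 arrays. There 932 shared direction with P35S:rGRF1 against Col-0 and 72 opposed, where independent lists would give 371 and 368. The r was 0.424 (0.5 simulated) and the covariance 0.135 (0.015 simulated). The 179 was 105, 108 and 100 without P35S:rGRF1 replicates 1, 2 and 3, 367 with array weights and 111 with the poly-A covariate.

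**Figure D3:**
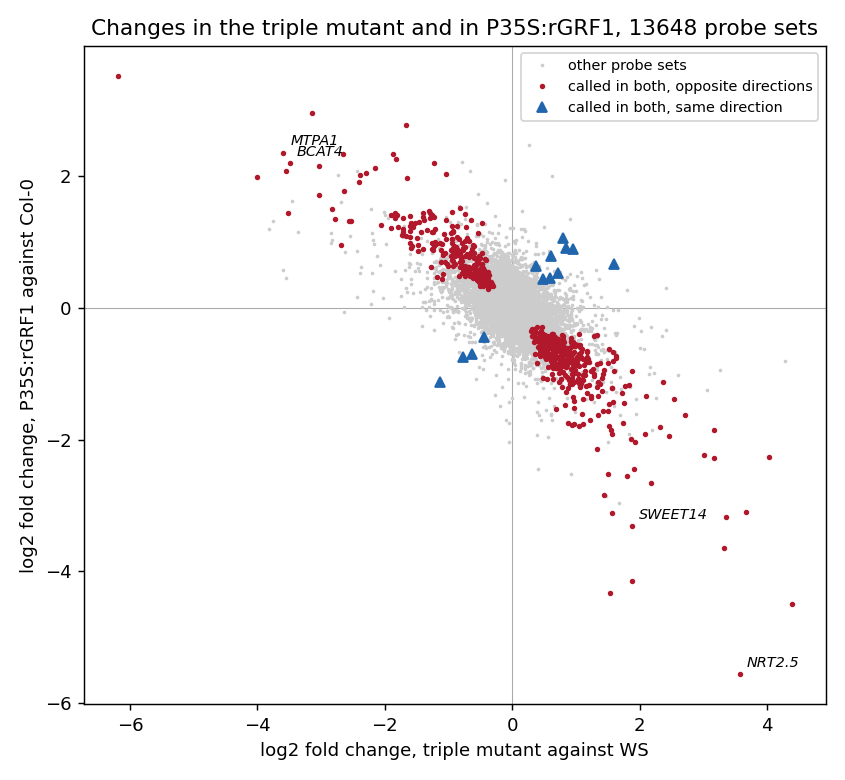
Log2 fold change of the triple mutant against WS (x axis) and of P35S:rGRF1 against Col-0 (y axis) for 13648 probe sets. Red points changed in both in opposite directions (605) and blue triangles in the same direction (13).

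MTPA1 and ZIP9 fell in the mutant and rose in P35S:rGRF3, as did AT5G48430 (-2.20 against WS and 1.39 against Col-0), while AT5G38710, AT1G66800 (1.2 and -1.32) and AT5G38020 (1.13 and -1.32) did the reverse. NRT2.5 rose in both, by 3.57 and 2.25. With the mutant against WS and P35S:rGRF3 against Col-0, 383 probe sets opposed and 97 shared direction, where independent lists would give 114 and 112, and r across probe sets was -0.215, or -0.0321 without Col-0 replicate 1. With the mutant called against both wild types and P35S:rGRF3 against WS, 242 opposed and 98 shared direction, where 177 and 176 would be given, and the WS arrays are shared. The 242 became 154, 143 and 136 without WS replicates 1, 2 and 3, and 158 without mutant replicate 2.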

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

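The tests on poly-A controls and on chromosome segments, and the splits of the designed comparisons, were planned before their results. All other tests of explanations here, and the split of the within-set overlap, were chosen only after the result was seen.

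The overexpression lines differed, by a test of the difference itself, at 2891 probe sets with both on arrays of 1 set. With each line against its labelled background, across the array sets, the test called 6657. That contrast also holds the difference between the wild types, called at 7058 probe sets. P35S:rGRF3 lay nearer Col-0 at 91.0% of the 310 probe sets that separated the wild types. The 6657 can therefore not be read as a difference of overexpression effects alone. The plastid-encoded genes had a median difference of 0.809 (log2) between the lines.

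Probe sets outside the comparisons also carried signal. The hybridization controls of the WS and mutant arrays were higher than those of the other 9 by 0.883 (log2). The 25S ribosomal RNA probe set stood at -1.29 in the mutant against WS and at 0.670 in P35S:rGRF1 against Col-0. The poly-A controls stood at 0.855 in P35S:rGRF1 against Col-0.

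P35S:rGRF3, labelled WS, lay close to Col-0. Within the Col-0 array set, 44 probe sets differed at least 4-fold from Col-0, and 45 did so for P35S:rGRF1, whose label is Col-0. The values are consistent with plants that carry Col-0 alleles at most loci. The mutant, on WS-set arrays, lay on the WS side at 85.2% of the 310 probe sets that separate the wild types, between the bounds set for and against the array set as the cause. A high value is also what WS alleles would give, so this test could only have argued against the array set. Those probe sets separate the wild types by at least 2 (log2), so a shift of 0.883, as in the hybridization controls, would not give them. The sets also differed in the 3' minus 5' signal of the poly-A controls, at 2.22 in WS and 2.04 in the mutant. It was 1.55 in Col-0, 1.66 in P35S:rGRF1 and 1.62 in P35S:rGRF3. How far such a difference moves single probe sets was not measured. Beyond a common shift of 0.883, the alleles and the array set cannot be told apart with these groups.

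Fold changes of the mutant against WS and of P35S:rGRF1 against Col-0 were opposite, with r of -0.649. With P35S:rGRF1 against Col-0, the mutant against Col-0 had a covariance of 0.0216 and WS against Col-0 one of 0.135. Both pairs cross the sets, and the shared Col-0 arrays alone gave 0.015 in simulated unchanged groups. The simulations gave all groups the same spread. Each Col-0 array differed from the other 2 with an SD of 0.402, 0.262 or 0.329, against 0.208 to 0.221 in P35S:rGRF1. The 0.015 may therefore be too low, and 0.0216 cannot be called above the level of shared arrays. The Col-0 array that lay apart, replicate 1, is argued against as the whole cause, since r was -0.529 without it. A scale factor per array adds a constant to log2 values and cannot change r, so r is no test of it. After quantile normalization r was -0.650, which argues only against differences in the shape of the signal distributions. The hybridization controls, which are added RNA, also moved opposite ways. They averaged 10.77 in the mutant and 11.02 in WS, and 10.14 in P35S:rGRF1 and 9.845 in Col-0. A technical difference between the arrays of these genotypes was not tested as a cause and cannot be told apart from genotype. The poly-A level, at its within-group slope plus 2 standard errors, would account for 35.4% of the plastid-encoded shift of P35S:rGRF1 and 8.68% of that of the mutant, so a part stays open. That slope rests largely on P35S:rGRF3, where the poly-A level had an SD of 1.12, against 0.132 to 0.505 in the other groups. Replicate 3 there read 6.961, and the plastid-encoded score had an SD of 0.013. The percentages therefore depend much on 1 array and are no firm bound. Opposite change of targets of the factors may contribute, but the 605 probe sets opposite and 13 alike are the pattern itself. No list of targets was used, so these counts do not tell this cause from others. The covariance of the pattern was -0.113, and its sign follows from WS against Col-0 having the larger covariance with P35S:rGRF1. A state of the roots that also varies within a genotype may contribute too. Col-0 replicate 1 against the other 2 correlated with the mutant's changes at r of 0.530. Replicates of P35S:rGRF3 gave 0.178, 0.199 and -0.318, and those of P35S:rGRF1 0.097, -0.0554 and -0.0454.

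In the mutant 17 of 158 markers lay nearer to Col-0 than to WS, though not all at the Col-0 level, among markers that separate the wild types by at least 2 (log2), a definition chosen after the data were seen. Segments of Col-0 sequence in a WS background could place such markers side by side. There were 3 neighbouring pairs, against a mean of 1.69 in 10000 random orders (p = 0.228, permutation test, one-sided). The bound written beforehand would have excluded segments at this p, but it was wrong for so few markers, because the pairs exceeded the random mean. With markers at 1.5 (log2), 8 pairs stood against a mean of 6.55 (p = 0.322, permutation test), and segments and scattered differences cannot be told apart.

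For comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The real split called 7058 probe sets for WS against Col-0, 6161 for the mutant against Col-0, 1429 for P35S:rGRF1 and 7147 for P35S:rGRF3 against WS, and the highest other split of each called 0. For the mutant against WS these numbers were 1900 and 1. In each, 1 split of 10 reached the real count, the real one itself.

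For results with more splits, 100 were drawn with the real one included. For the difference of effects between the lines (6657, highest other 2593) a random grouping of all 12 arrays was excluded. But the splits exchange arrays across the 2 sets and the wild types, and the real value crosses the sets. The wild types alone differed at 7058 probe sets. This result does not separate a difference between the lines from the array sets or from the wild types. For the opposite changes of the mutant with P35S:rGRF1 (179, highest other 0) and with P35S:rGRF3 (242, highest other 0), none (0) of the 99 other splits called probe sets in both comparisons, so no overlap was possible and these splits say nothing about direction. Nearly the same holds for the within-set opposite changes (605, highest other 0), where the shorter list of any other split held at most 1. The 174 probe sets of shared direction in the lines also exceeded the highest other split (103), but 4 of the other splits called probe sets in both lists, and independent lists of the real sizes would give 373, so they show no excess of sharing. In each, 1 split of 100 reached the real value. For the mutant against both wild types (675), 2 of 100 did, which excludes a random grouping of the 9 arrays but not the array sets. The wild types among these arrays already differed at 7058 probe sets. So a random grouping was false whatever the mutant did, and this result does not show an effect of the mutant. The highest other split called 4716. That split set all 3 Col-0 arrays against mixtures of WS and mutant arrays, which follows the array sets and points to a structure of the samples, and the value within 1 set is 1900. The split with 2593 kept the 3 WS arrays together.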

How the results depend on the processing

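The comparisons within array sets, Col-0 as the control for P35S:rGRF3 and the poly-A covariate were chosen after the data were seen; the other settings were planned. The named genes were chosen as called, with the largest changes, on these same arrays, so reversals were unlikely from the start. Of 2770 values for named genes under alternatives, 2695 kept direction and side of the threshold, 75 fell short of it and 0 reversed. Of 660 values for gene lists 620 did so, 35 were lost (27 of them by the estimated correlation), 5 were gained and 0 reversed. Of 260 counts 205 stayed within 1.5 times. Dim signals limit the folds, with no detection calls used here.

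With a minimum change of 1.5-fold, which can only remove calls, the counts were 4347 for WS against Col-0, 3810 for the mutant against Col-0, 1233 against WS and 446 against both, 868 for P35S:rGRF1, 4588 for P35S:rGRF3 against WS and 964 against Col-0, and 1632 between the lines. The overlaps were 101 (same direction in both lines), 126 (mutant and P35S:rGRF3 opposed) and 374 (within-set opposed).

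With array weights the counts were 1179 for the mutant against both wild types, 3017 for P35S:rGRF1, 336 for the same direction, 367 for the mutant and P35S:rGRF1 opposed and 1131 within sets. With the poly-A covariate they were 757 for P35S:rGRF1, 1330 between the lines, 108 for the same direction, 111 for the mutant and P35S:rGRF1 opposed and 369 within sets. With only the arrays of the groups compared, and so fewer samples, they were 919 for P35S:rGRF1 and 621 for P35S:rGRF3 against Col-0. For array weights and the covariate the cause was not tested.

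With Col-0 as control, P35S:rGRF3 gave 1626, the difference between the lines 2891, the same direction 301 and the mutant and P35S:rGRF3 opposed 130. Within array sets, the opposed counts were 605 for P35S:rGRF1 and 383 for P35S:rGRF3.

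Leaving out 1 array, the counts ran from 6218 to 6547 for WS against Col-0, 5103 to 6239 for the mutant against Col-0, 1158 to 1392 against WS and 466 to 1000 against both. They ran from 586 to 1554 for P35S:rGRF1, 6345 to 6794 for P35S:rGRF3 against WS, 973 to 1793 against Col-0, 1672 to 2897 between the lines and 5947 to 6604 for the difference of effects. The overlaps ran from 82 to 212 (same direction), 100 to 172 (opposed, P35S:rGRF1), 136 to 310 (opposed, P35S:rGRF3) and 322 to 751 (within sets). Without Col-0 replicate 1 P35S:rGRF1 had 658, of which 605 were among the 1429.

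With the replicate block the counts were 6928, 6033, 1796 and 654 for WS against Col-0 and the mutant against Col-0, WS and both, 1327 for P35S:rGRF1, 7033 and 1549 for P35S:rGRF3 against WS and Col-0, 6528 for the difference, 2766 between the lines, and 185, 185, 234 and 570 for the overlaps. Of 30 correlations of same-numbered arrays 6 were over 0.1. Each array was also set against the arrays of each other genotype. In 21 of 60 such cases it correlated best with the array of its own number, so the numbers do not pair the arrays. The block ended the ATG8 call in P35S:rGRF1 and gave a SWEET call in the mutant against WS.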

Other observations

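The correlations within genotypes in this part were chosen after the result was seen.

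Of 5 GH9 cellulase genes 3 were higher and 0 lower in the mutant than in Col-0, with a median of 0.57 (adjusted p = 0.255 for the list), and 0 passed in either direction against WS (adjusted p = 0.540). Of 16 TBL genes 6 were higher and 0 lower than in Col-0 (adjusted p = 0.255). Of 6 core histone genes 3 were higher and 1 lower than in Col-0 (adjusted p = 0.748), and 0 passed against WS (adjusted p = 0.865). The comparisons with Col-0 cross the array sets. Of 12 glutathione transferase genes 2 rose and 2 fell in the mutant against WS (adjusted p = 0.510 for the list), among them GSTU20 at -0.94, and 1 rose and 2 fell in P35S:rGRF1 (adjusted p = 0.102). Of 16 serine carboxypeptidase-like genes 5 rose and 1 fell in P35S:rGRF1 (adjusted p = 0.220). Beta-glucosidases (1 of 7 higher and 2 lower in the mutant against WS, adjusted p = 0.576), xyloglucan endotransglucosylases (0 of 8 higher and 2 lower, adjusted p = 0.510) and tetraspanins (2 of 7 higher and 0 lower, adjusted p = 0.540) did not pass as lists there. Of 7 U-box ligase genes 4 were lower in WS than in Col-0 and 1 higher, PUB22 by -1.46 and PUB24 by -1.77 (adjusted p = 0.0949).

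Single genes of lists too small to test also differed between the wild types. The immune regulator gene WRKY53 was lower in WS by -1.68 (adjusted p = 8.83e-04), the zinc finger gene STZ by -2.07 and the root transcription factor gene UPB1 by -1.35. PRL, of the replication licensing family, was higher by 1.12. In P35S:rGRF1 against Col-0, UPB1 fell by 0.88 (adjusted p = 0.0158) and PRL rose by 0.53 (adjusted p = 0.0186).

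The nitrate transporter genes varied between arrays of Col-0. NRT2.5 read 11.56, 10.56 and 9.31 (log2 signal) and AT3G21670 read 9.84, 8.57 and 8.10 on replicates 1 to 3, and AT3G25790 read 6.17, 7.72 and 7.67. Replicate 1 lay nearest to the mutant at each of these genes except NRT2.5, and across all probe sets each Col-0 replicate against the other 2 gave r of 0.530, -0.202 and -0.487 with the mutant's changes against WS. The same measure gave 0.178, 0.199 and -0.318 in P35S:rGRF3. With the changes of P35S:rGRF1 against Col-0 it gave -0.0758, -0.282 and 0.297 in P35S:rGRF3, 0.0411, -0.198 and 0.135 in WS and 0.0555, 0.0296 and -0.0823 in the mutant. The genes did not move together in P35S:rGRF3, where NRT2.5 read 12.59, 13.10 and 12.48, above every Col-0 array, and AT3G21670 read 7.62, 7.61 and 7.15, below every one. No explanation was tested for these genes.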
